A study of Caenorhabditis elegans with 18 samples.

How the data were processed

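RNA was taken from whole L4 animals of 3 genotypes under 3 treatments, after L1 larvae had been synchronized by 18 hours of arrest, and the libraries were made by a sequencing company, per the labels' protocols. The deposited table holds FPKM values, fragments per kilobase of gene scaled to the library's total, made by the authors for 20953 genes in 18 libraries, 1 column per library, with replicates kept apart. Per the submitters' processing notes the tools were HISAT, Bowtie2 and RSEM and the genome build WBcel235; their versions, their settings, any filter and whether strand was used are not given in the sources used here. RSEM shares reads that map to several genes between them by a statistical estimate. Values of near-identical copies (acdh-1 and acdh-2, the msp genes among the sperm markers, vit-3, vit-4 and vit-5, sams-1 and its relatives, the hsp-16 genes) and of overlapping genes are therefore uncertain. Because FPKM divides by the library's total, a change in a few abundant genes shifts all others.

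Columns were matched to samples by name, and groups were taken from the labels. Gene names and coordinates came from the Ensembl release 115 annotation of WBcel235, in which 208 of the table's gene identifiers were not found; 19090 had a symbol, 19093 were protein-coding and 1632 were listed as pseudogenes. 130 genes were at 0 in every library. No genome sequence was used here, so GC content was not checked. The table gives no counts. Depth was estimated from the FPKM step of genes with 1 transcript, with 30 bp taken off each length, as about 12600000 to 14200000 fragments; 1 fragment then adds under 0.1 FPKM to a gene of average length, and values near that step rest on few fragments. Replicate spread was not set against counting error.

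Genes with at least 1 FPKM in at least 2 libraries were kept (15575), values were put on the log2(FPKM + 1) scale, and limma 3.58.1 in R 4.3.3 was fitted with a mean for each of the 9 groups and an intensity trend in the variance prior, so that all groups share an estimate of the spread (9 residual and 3.60 prior degrees of freedom). A log2 difference on this scale understates the change of genes near or under 1 FPKM. The 19 comparisons were the B12 and propionate responses in each genotype, B12 with propionate against untreated in wild type, each mutant against wild type in each treatment, the mutants against each other untreated and on B12 with propionate, and the 4 differences between a mutant's and the wild type's response. Adjusted p-values follow Benjamini and Hochberg over all genes of a comparison, and a gene is called higher or lower under 0.05. Means are given with the SD of the 2 libraries and log2 differences with limma's SE. Levels of single libraries are given where a group is listed at or near 0.

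The 28 gene lists were the propionate shunt, canonical B12-dependent propionate breakdown, the methionine and S-adenosylmethionine cycle, branched-chain amino acid breakdown, glycine cleavage, mitochondrial and peroxisomal fatty acid oxidation, fatty acid synthesis and desaturation, the tricarboxylic acid and glyoxylate cycle, the mitochondrial and endoplasmic reticulum unfolded protein responses, heat shock, oxidative stress, cytochrome P450 genes, UDP-glucuronosyltransferases, innate immunity, hypoxia and hydrogen sulphide, cytosolic ribosomal proteins, nuclear hormone receptors, vitellogenins, sperm, oocyte and germline, intestine, moulting, body wall muscle, pharynx and neuron markers, and cuticle collagens. The shunt list comes from earlier work on this network and so is not independent of what is known about B12. Each list was tested with camera in limma at its preset correlation of 0.01 and again with a correlation estimated from the data, with Benjamini-Hochberg adjustment over all 532 list tests, and its members were also adjusted over the list alone.

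Groups, comparisons, lists, tests, alternatives and the rule for the genes to be named were fixed before the data were examined. Named are nhr-10, nhr-68 and the members of both propionate lists in every comparison; the 10 largest rises and 10 largest falls among called genes whose libraries do not overlap between groups, or fewer where space is short; up to 4 members of each list with the smallest adjusted p; and the regulators nhr-114, nhr-49, nhr-66, nhr-80, nhr-13, nhr-8, nhr-86, mdt-15 and sbp-1. Genes named outside this rule were chosen after their values were seen: the 4 whose B12 response differed in nhr-10 mutants, those plotted or listed because they separate the mutants on propionate, and those kept with the stage axes as covariates.

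The alternatives fixed in advance were a pseudocount of 0.1, no low-value filter, median-ratio scaling of the libraries, only the compared groups in the fit, the replicate number as a block, an estimated correlation for the lists, and leaving out each library of a comparison in turn. In the last of these a group is left with 1 library, which is taken to vary like the other groups. A fit with the leading pair of principal components of the 160 collagen, moulting and vitellogenin genes as covariates was added after the data were seen. Overlaps between comparisons with common control libraries were set beside 100 draws of simulated unchanged groups. The fit was tested on simulated data for B12 against untreated in wild type, with 15575 genes of which 200 were changed and 20 draws. It recovered 48.7% of genes changed 2-fold, 94.1% of those changed 4-fold and 98.6% of those changed 8-fold. False calls made up 5.27% of calls, with 0 calls in an unchanged comparison. Genes varied independently in all of these simulations, so no simulated library shifted as a whole. Where real replicates stood apart along the stage axes, these rates need not carry over. A 2-fold shift put on the shunt list in the B12 comparison of nhr-68 mutants was found in 20 of 20 draws. This was counted with camera at its preset correlation and an unadjusted p under 0.05. Camera with an estimated correlation and adjustment over all list tests was not tried in these draws. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.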

Results

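Transcript levels were measured by RNA sequencing in whole Caenorhabditis elegans animals, each library made from about 3000 animals collected at the L4 larval stage. The 18 libraries form 9 groups of 2: 3 genotypes crossed with 3 treatments. The genotypes are the laboratory wild type N2, a deletion in nhr-10 and a deletion in nhr-68. Both genes encode nuclear hormone receptors, a family of ligand-regulated transcription factors. Animals were left untreated on plates without added vitamin B12, given 20 nM vitamin B12, or given 20 nM vitamin B12 with 40 mM propionate for 48 hours. Propionate is a short-chain fatty acid made when some amino acids and odd-chain fatty acids are broken down. It is degraded by a canonical pathway that needs B12, and by a B12-independent route called the propionate shunt, whose enzymes are encoded by acdh-1, ech-6, hach-1, hphd-1 and alh-8. The study asks how the animal rewires this network when propionate builds up and what nhr-10 and nhr-68 contribute. Total FPKM (fragments per kilobase of gene, scaled to the library's total) lay between 841999.6 and 920001.8 per library, and between 13753 and 14732 genes reached 1 FPKM. The step size of low FPKM values implies about 12600000 to 13100000 fragments in the wild type libraries, 12900000 to 13200000 in the nhr-10 libraries and 13900000 to 14200000 in the nhr-68 libraries. The labels do not say that the replicates come from separate cultures, so all p-values measure the spread between these samples, which may be technical in part.

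The deleted genes were read out first. nhr-68 (chromosome V, 11573440 to 11575709 of WBcel235) was at 14.95 and 11.6 FPKM in the untreated nhr-68 mutants against 108.25 and 88.46 in wild type. On B12 it was at 1.71 and 2.49 against 48.69 and 50.37, and on B12 with propionate at 2.1 and 3.99 against 53.54 and 55.94. In the nhr-10 mutants nhr-68 was at 79.06 and 140.23 FPKM untreated, 5.18 and 13.06 on B12, and 10.75 and 18.19 on B12 with propionate. nhr-10 (III, 7112295 to 7115438) was at 6.14 and 9.9 FPKM in the untreated nhr-10 mutants, 7.25 and 7.4 on B12, and 9.29 and 10.33 on B12 with propionate. The wild type values of nhr-10 were 17.23 and 15.08 untreated, 19.78 and 12.23 on B12, and 33.45 and 14.88 on B12 with propionate, and those of the nhr-68 mutants lay between 16.9 and 21.82. Each nhr-10 library was thus below each library of the other genotypes, although reads still fell on the gene, whose values are summed over its whole length. The labels do not say which part is deleted. The log2 difference of nhr-10 between nhr-10 mutants and wild type was -0.96 untreated, -0.99 on B12 and -1.12 on B12 with propionate, with limma adjusted p-values (Benjamini-Hochberg) of 0.166, 0.066 and 0.0518.

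Pearson's r across genes between the log2 values of replicates lay between 0.9695 and 0.9859. The leading principal components carried 35.2% and 18.8% of the variance. A pair of axes drawn from the 160 tested collagen, moulting and vitellogenin genes, families that change with stage, carried 61.6% and 26.9% of their variance. On these axes replicates of a group could lie far apart: replicate 2 of the nhr-10 mutants on B12 with propionate stood at -17.8 and 21, and replicate 1 of the nhr-10 mutants on B12 at 16.9 on the leading axis. Wild type on B12 with propionate stood at -9.63 in replicate 1 and at 2.94 in replicate 2. Where leaving out a library moves the number of genes called in a comparison by more than 1.5 times, the library is named below with the number that is left; counts shared between comparisons are given with the lowest and highest.

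Vitamin B12 lowered every shunt gene in wild type. acdh-1 (I, 6497436 to 6499560), an acyl-CoA dehydrogenase at the entry of the shunt, fell from 2303 ± 347 FPKM untreated to 90.8 ± 35.8 on B12 (SD, n = 2), and its log2 change was -4.70 ± 0.315 (SE; limma, Benjamini-Hochberg adjusted p = 3.5e-05). The enoyl-CoA hydratase gene ech-6 (III, 9751552 to 9752883) fell from 789 ± 223 to 175 ± 2.96 FPKM, the hydrolase gene hach-1 (III, 5555450 to 5557318) from 267 ± 88.2 to 67.2 ± 3.80, and the transhydrogenase gene hphd-1 (II, 12994354 to 12996571) from 377 ± 73.9 to 78.9 ± 0.495. The fall of alh-8 (II, 11729055 to 11731198), a semialdehyde dehydrogenase gene, was smaller (log2 -0.67 ± 0.133), and its call ended whichever of the 4 libraries was left out, with adjusted p between 0.129 and 0.262 in limma. All 5 members of the shunt list fell, as they did when adjusted over the list alone; the list's adjusted p was 0.0877 with an estimated correlation. Of the methionine cycle, 7 of 19 members fell and 1 rose, and adjusted over the list alone 11 fell and 1 rose (adjusted p = 0.247 with an estimated correlation). mtrr-1, the reductase that keeps methionine synthase active, fell from 143 ± 25.4 to 24.4 ± 1.65 FPKM, metr-1, the B12-dependent methionine synthase itself, from 140.5 ± 16.39 to 32.2 ± 0.325, and folt-2, a folate transporter gene, from 294 ± 31.3 to 90.4 ± 12.3. Also lower were the C-type lectin gene clec-47 (log2 -6.0 ± 0.508), the methionine sulfoxide reductase gene msra-1 (-3.04 ± 0.321) and acdh-2 (-3.53 ± 0.426), whose near-identical copy acdh-1 makes its reads uncertain. Higher were the glutathione S-transferase genes gst-38 (2.20 ± 0.202) and gst-20 (1.84 ± 0.199) and the immune response gene dod-24 (2.04 ± 0.218). Of 17 innate immunity genes 3 rose, and adjusted over the list alone 9 rose and 1 fell (adjusted p = 0.177 with an estimated correlation).

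In all, 43 genes were higher and 53 lower on B12 among 15575 tested in limma with Benjamini-Hochberg adjustment, 36 and 47 of them by at least 2-fold, and 55 and 49 with median-ratio scaling. The total of 96 became 24 without wild type untreated replicate 1, 38 without untreated replicate 2, 34 without B12 replicate 2 and 12 with only these groups in the fit, and 17 of 36 named genes kept their call in each of the 4 fits that left out a library, all those printed with a value above among them except alh-8. Of the 45 sperm markers 1 fell, and adjusted over the list alone 32 did (adjusted p = 0.416 with an estimated correlation). Of the 7 genes of the canonical pathway 1 fell, and adjusted over the list alone 2 fell and 1 rose. Heat shock genes had no call among 10 members, although hsp-16.2 stood at 76.05 FPKM in B12 replicate 1 and at 0 in B12 replicate 2.

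Propionate given with B12 brought the shunt back up in wild type. acdh-1 rose from 90.8 ± 35.8 to 1734 ± 476 FPKM (SD, n = 2; log2 4.27 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 5.47e-05), ech-6 from 175 ± 2.96 to 871 ± 38.8, hach-1 from 67.2 ± 3.80 to 466 ± 16.9, hphd-1 from 78.9 ± 0.495 to 379 ± 73.5 and alh-8 from 298 ± 27.2 to 573 ± 12.04. Steeper still was acdh-2 (II, 5544778 to 5547492; log2 4.95 ± 0.426). C09B8.4 (X, 6018442 to 6019936), a gene of unknown function, rose by 3.91 ± 0.265, from 0.92 ± 0.269 to 27.7 ± 0.212 FPKM. The arginine kinase gene argk-1 (3.48 ± 0.324), the secreted immunoglobulin-domain gene zig-3 (3.31 ± 0.358), the cystathionine lyase gene cth-1 (1.89 ± 0.231) and folt-2 (1.84 ± 0.200) rose as well. C17H12.8, a pathogen response gene, fell from 531 ± 37.2 to 124 ± 9.86 FPKM, and gst-38 fell by 1.70 on the log2 scale (SE 0.202). All 5 shunt genes rose, also when adjusted over the list alone, with adjusted p = 0.107 with an estimated correlation. Of 17 innate immunity genes 5 fell, and adjusted over the list alone 10 fell and 1 rose (adjusted p = 0.158 with an estimated correlation). Of 17 genes of mitochondrial fatty acid oxidation 2 rose, and adjusted over the list alone 4 rose and 2 fell.

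Propionate raised 42 genes and lowered 22 in wild type (limma, Benjamini-Hochberg), 37 and 17 by at least 2-fold, and with median-ratio scaling 45 rose and 46 fell. The total of 64 became 143 without B12 replicate 1, 24 without B12 replicate 2, 286 without propionate replicate 1 and 28 without propionate replicate 2, and further 120 with a pseudocount of 0.1, 109 with the replicate number as a block, 25 with both stage axes as covariates, a fit chosen after the data were seen, and 2 with only these groups in the fit. Of 30 named genes 15 kept their call in each of the 4 fits without a library. Among the shunt genes only alh-8 lost it in these 4, with a limma adjusted p of 0.0592 without propionate replicate 2. Sperm markers had no call among 45 genes, and adjusted over the list alone 21 rose (adjusted p = 0.668 with an estimated correlation). The 2 wild type responses ran in opposite directions: 8 genes were higher on B12 and lower with propionate, and 14 the reverse, where independent lists of these sizes would share 0.0607 and 0.143. Together these 22 ran from 10 without B12 replicate 2 to 43 without B12 replicate 1, and were 37 with the replicate number as a block and 10 with the stage axes as covariates. The correlation of the log2 changes across genes was -0.689 against -0.499 in simulated unchanged groups sharing the same B12 libraries, and the covariance -0.129 against -0.0439. The 2 shared libraries cannot be split, so part of the excess may come from them.

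Against untreated animals, wild type on B12 with propionate had acdh-1, ech-6, hphd-1 and alh-8 near their untreated level, while metr-1 and mtrr-1 stayed low. acdh-1 was at 1734 ± 476 FPKM against 2303 ± 347 (SD, n = 2; log2 -0.43, 95% interval -1.11 to 0.25), hphd-1 at 379 ± 73.5 against 377 ± 73.9 (0.01, -0.51 to 0.52), and ech-6 and alh-8 differed by 0.17 and 0.27. None of the 5 shunt genes passed the test over all genes, and hach-1 (0.84 ± 0.22, SE) was the member that passed when adjusted over the list alone. metr-1 was lower by -2.18 ± 0.214 and mtrr-1 by -1.99 ± 0.195, and of 19 methionine cycle genes 7 fell and 1 rose, 10 and 1 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). clec-47 (-5.76 ± 0.508) and msra-1 (-3.31 ± 0.321) were also lower. argk-1 (4.14 ± 0.324), the lipase gene lipl-2 (2.81 ± 0.321), C09B8.4 (2.50 ± 0.265), cth-1 (2.09 ± 0.231) and the carnitine acyltransferase gene cpt-5 (1.69 ± 0.188) were higher. In limma with Benjamini-Hochberg adjustment 20 genes were higher and 26 lower, 18 and 23 by at least 2-fold. That total of 46 became 16 without untreated replicate 1, 19 without untreated replicate 2, 19 without propionate replicate 1 and 0 with only these groups in the fit (639 at an unadjusted limma p under 0.05), and 13 of 24 named genes, including those printed here with a call, kept it in each of the 4 fits without a library.

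**Figure D1:**
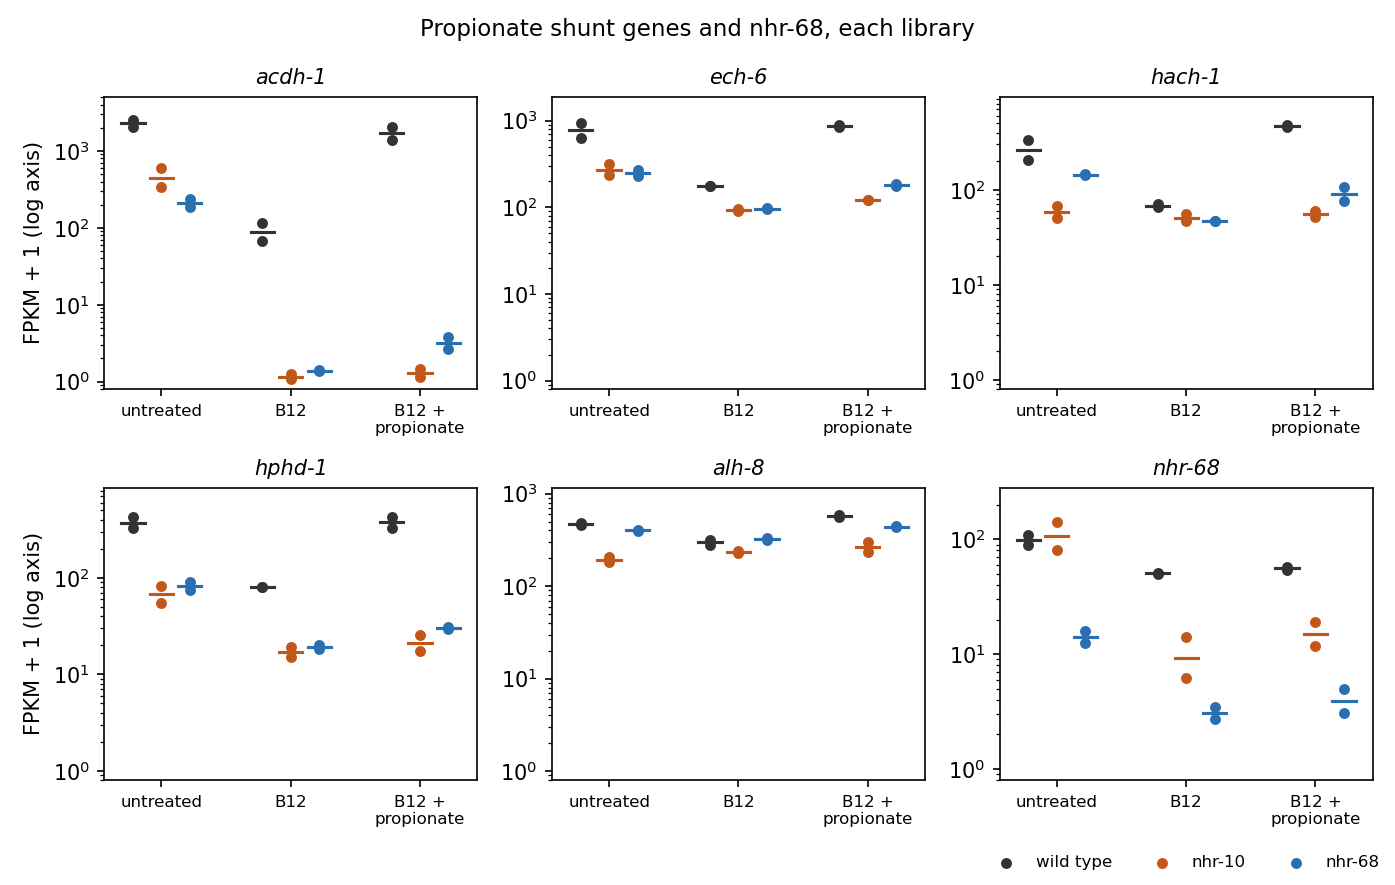
FPKM + 1 on a log axis of the shunt genes and nhr-68 in each treatment, with points for single libraries, in wild type (black), nhr-10 mutants (orange) and nhr-68 mutants (blue). Bars give the mean of the 2 libraries on the log2(FPKM + 1) scale, so the FPKM means quoted can lie above them. acdh-1 lies at 1734 ± 476 FPKM in wild type on B12 with propionate, at 0.3 ± 0.198 in nhr-10 mutants and at 2.22 ± 0.757 in nhr-68 mutants.

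In nhr-10 mutants B12 silenced acdh-1 almost fully. It fell from 462 ± 182 to 0.16 ± 0.127 FPKM (SD, n = 2; log2 -8.59 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 2.2e-08), while ech-6 fell from 274 ± 54.3 to 92.2 ± 2.81 and hphd-1 from 67.7 ± 19.5 to 16.15 ± 3.04. hach-1 (log2 -0.21 ± 0.22) and alh-8 (0.28 ± 0.133) did not pass. nhr-68 itself fell from 110 ± 43.3 to 9.12 ± 5.57 FPKM (-3.51 ± 0.381). The methionine cycle genes metr-1 (-2.79 ± 0.214), mtrr-1 (-2.68 ± 0.195), mel-32, a serine hydroxymethyltransferase gene (-1.26 ± 0.153), and ahcy-1, the S-adenosylhomocysteine hydrolase gene (-1.41 ± 0.176), fell too, as did msra-1 (-4.93 ± 0.321) and clec-47 (-6.18 ± 0.508). The immune gene irg-3 rose (1.46 ± 0.178). Of 5 shunt genes 3 fell, also adjusted over the list alone (adjusted p = 0.305 with an estimated correlation). Of 19 methionine cycle genes 7 fell and 1 rose, 10 and 3 adjusted over the list alone (adjusted p = 0.416 with an estimated correlation). Of 58 UDP-glucuronosyltransferases 4 fell, 9 adjusted over the list alone (adjusted p = 0.745 with an estimated correlation).

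The count was 30 higher and 92 lower (limma, Benjamini-Hochberg), 23 and 81 by at least 2-fold, and 57 and 81 with median-ratio scaling. The median of all genes was -0.117 in this comparison. Its total of 122 became 47 without nhr-10 untreated replicate 2, 47 without nhr-10 B12 replicate 1, 64 with the stage axes as covariates and 21 with only these groups in the fit, and 18 of 38 named genes, including all of those just given with a call, passed in each of the 4 fits without a library. Set against wild type, the B12 response of the nhr-10 mutants differed in 4 genes, named here because they are so few: acdh-1 (-3.89 ± 0.446), zig-3 (3.67 ± 0.506), F55G11.2 (-1.77 ± 0.176) and F14F9.4 (-1.6 ± 0.208). At an unadjusted limma p under 0.05 there were 1374. The shunt genes hach-1 (1.73 ± 0.311), alh-8 (0.95 ± 0.189) and ech-6 (0.59 ± 0.254) were among these. Their unadjusted limma p-values were 0.000105, 0.00024 and 0.0375, and their adjusted ones over all genes 0.128, 0.173 and 0.551. For hphd-1 (0.24 ± 0.337) the unadjusted limma p was 0.481. F55G11.2 passed in all 8 fits without a library. acdh-1 missed the threshold without nhr-10 B12 replicate 1 (limma adjusted p = 0.0765), where 1 gene was left, and 17 were called without wild type B12 replicate 1. Without wild type untreated replicate 1, wild type B12 replicate 2 or nhr-10 untreated replicate 1 there were 2. zig-3 passed in 1 of the 8 fits and F14F9.4 in 2. With only these groups in the fit none of the 4 passed (limma adjusted p between 0.296 and 0.371). zig-3 also missed with a pseudocount of 0.1 (0.113) and without the low-value filter (0.0539), and F14F9.4 with the stage axes as covariates (0.236).

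Propionate did not raise the shunt in nhr-10 mutants. acdh-1 was at 0.3 ± 0.198 FPKM against 0.16 ± 0.127 on B12 alone (SD, n = 2; log2 0.16, 95% interval -0.52 to 0.84), ech-6 at 121 ± 1.05 against 92.2 ± 2.81, and none of the 5 shunt genes passed over all genes or adjusted over the list alone. Other genes did respond. far-3, which encodes a fatty acid and retinol binding protein, rose from 10.9 ± 8.24 to 427 ± 44.3 FPKM, argk-1 from 15.2 ± 0.495 to 135 ± 38.5 and gst-4, a glutathione S-transferase gene, from 105 ± 27.6 to 450 ± 89.5. C45B2.2 (3.47 ± 0.262, SE), the cytochrome P450 gene cyp-13B1 (3.50 ± 0.361) and cpt-5 (1.46 ± 0.188) rose, and gldc-1 of the glycine cleavage system fell from 84.6 ± 3.70 to 35.8 ± 0.247 FPKM. Of 17 genes of mitochondrial fatty acid oxidation 6 rose, and adjusted over the list alone 8 rose and 1 fell (adjusted p = 0.58 with an estimated correlation). Of 9 hypoxia and hydrogen sulphide genes 3 rose, 6 adjusted over the list alone (adjusted p = 0.52 with an estimated correlation). Of the canonical pathway's 7 genes pccb-1 (0.83) and pcca-1 (0.65), the subunits of propionyl-CoA carboxylase, rose, 3 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation). In glycine cleavage 2 of 4 genes fell, also adjusted over the list alone (adjusted p = 0.362 with an estimated correlation).

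Stage-linked groups moved in the same comparison: all 6 vitellogenins, the yolk protein genes, fell, also adjusted over the list alone (adjusted p = 0.506 with an estimated correlation), 8 of 16 moulting markers rose, 12 adjusted over the list alone (adjusted p = 0.58 with an estimated correlation), and of 138 cuticle collagens 17 rose and 33 fell, 32 and 44 adjusted over the list alone. In total 709 genes were higher and 418 lower (limma, Benjamini-Hochberg), 480 and 284 by at least 2-fold. The 1127 became 118 without nhr-10 B12 replicate 1 and 65 without nhr-10 propionate replicate 2, the library at the end of the stage axes. Of 77 named genes 12 passed in each of the 4 fits without a library, the 7 above with an SD or SE among them, whereas without propionate replicate 2 pccb-1 (0.68, limma adjusted p = 0.222), pcca-1 (0.49, 0.295) and the vitellogenin vit-6 (-1.89, 0.318) did not pass. Both stage axes as covariates left 8 genes, among them gst-4 (2.06) and C45B2.2 (2.85), and 0 with only these groups in the fit (2629 at an unadjusted limma p under 0.05).

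The test of the difference between the propionate responses of nhr-10 mutants and wild type put numbers on the missing shunt response. The log2 difference was -4.11 ± 0.446 (SE) for acdh-1, -1.92 ± 0.254 for ech-6, -2.66 ± 0.311 for hach-1, -1.93 ± 0.337 for hphd-1 and -0.77 ± 0.189 for alh-8, with limma adjusted p-values (Benjamini-Hochberg) of 0.00183, 0.00625, 0.00349, 0.015 and 0.0358. All 5 fell short of wild type, also adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). sams-1, which encodes an S-adenosylmethionine synthetase, went the other way (2.64 ± 0.394). Of 7 canonical pathway genes 3 had a higher response, also adjusted over the list alone (adjusted p = 0.58 with an estimated correlation). Of the stage-linked lists, 24 of 45 sperm markers, 7 of 20 oocyte and germline markers and all 6 vitellogenins had a lower response, 40, 14 and 6 adjusted over the list alone (adjusted p = 0.506, 0.58 and 0.58 with an estimated correlation). The whole set was 550 higher and 773 lower, and 800 and 722 with median-ratio scaling. Without a library the 1323 became 856 (wild type B12 replicate 1), 58 (wild type B12 replicate 2), 2258 (wild type propionate replicate 1), 45 (wild type propionate replicate 2), 53 (nhr-10 B12 replicate 1) or 60 (nhr-10 propionate replicate 2). They became 645 without the low-value filter and 4 with only these groups in the fit. acdh-1, ech-6, hach-1 and sams-1 passed in all 8 fits without a library, hphd-1 in 7 (limma adjusted p = 0.0635 without wild type B12 replicate 2) and alh-8 in 2. With the stage axes as covariates 2 genes were left, acdh-1 (-5.49) and hphd-1 (-3.26).

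B12 lowered shunt and methionine genes in nhr-68 mutants too. acdh-1 fell from 212 ± 35.3 to 0.39 ± 0.0424 FPKM (SD, n = 2; log2 -7.25 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 1.64e-07), ech-6 from 247 ± 27.2 to 95.4 ± 2.998, hach-1 from 143 ± 3.46 to 45.8 ± 0.0283 and hphd-1 from 81.6 ± 11.7 to 18.2 ± 1.14. acdh-2 fell from 158 ± 11.6 to 1.24 ± 0.813 FPKM, C09B8.4 from 79.1 ± 2.69 to 0.495 ± 0.587, and folt-2 from 130 ± 7.09 to 10.8 ± 1.76. metr-1 (-2.15 ± 0.214), mtrr-1 (-1.81 ± 0.195), ahcy-1 (-1.28 ± 0.176), msra-1 (-4.03 ± 0.321) and clec-47 (-6.90 ± 0.508) fell, and lipl-2 (2.44 ± 0.321) and irg-3 (1.52 ± 0.178) rose. Of the 5 shunt genes 4 fell, and 5 adjusted over the list alone (adjusted p = 0.0877 with an estimated correlation). Of 19 methionine cycle genes 6 fell and 1 rose, 9 and 2 adjusted over the list alone (adjusted p = 0.408 with an estimated correlation). Of 178 nuclear hormone receptors 4 fell, 5 adjusted over the list alone (adjusted p = 0.773 with an estimated correlation), among them nhr-156 (-2.23 ± 0.219). The 39 genes higher and 78 lower (limma, Benjamini-Hochberg; 34 and 66 by at least 2-fold) became 58 without untreated replicate 1, 46 without untreated replicate 2, 56 without B12 replicate 1 and 53 without B12 replicate 2, and 19 of 39 named genes, including all those given here with a fall or rise, passed in each fit without a library. The B12 response differed from that of wild type in 1 gene, C09B8.4 (-4.40 ± 0.375, limma adjusted p = 0.00059), which passed in all 8 fits without a library but not with a pseudocount of 0.1 (-5.49 ± 0.959, limma adjusted p = 0.161) or with only these groups in the fit (0.0528). On B12 the means of C09B8.4, 0.92 ± 0.269 FPKM in wild type and 0.495 ± 0.587 in nhr-68 mutants, lie where the pseudocount weighs most. Of the shunt genes, acdh-1 (-2.55 ± 0.446) and ech-6 (0.78 ± 0.254) did not pass for this difference (limma adjusted p = 0.146 and 0.675). Their unadjusted limma p-values were 7.86e-05 and 0.00943, and those of hach-1, hphd-1 and alh-8 were 0.331, 0.71 and 0.0749. Calls numbered 7 without the low-value filter, 5 with median-ratio scaling and 2 with the stage axes as covariates; 2 genes were called without wild type untreated replicate 2, and 887 had an unadjusted p under 0.05.

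Propionate in nhr-68 mutants left acdh-1 near its low level but raised other genes of the wild type response. acdh-1 was at 2.22 ± 0.757 FPKM against 0.39 ± 0.0424 (SD, n = 2; log2 1.19, 95% interval 0.51 to 1.87; limma, Benjamini-Hochberg adjusted p = 0.2). ech-6 (0.91), hach-1 (0.95), hphd-1 (0.65) and alh-8 (0.43) did not pass over all genes, and all 5 shunt genes did when adjusted over the list alone (adjusted p = 0.232 with an estimated correlation). acdh-2 rose from 1.24 ± 0.813 to 158 ± 101 FPKM, C09B8.4 from 0.495 ± 0.587 to 79.0 ± 25.2, folt-2 from 10.8 ± 1.76 to 74.9 ± 23.3, the short-chain dehydrogenase gene dhs-25 from 62.2 ± 8.11 to 267 ± 42.2 and the UDP-glucuronosyltransferase gene ugt-53 from 3.96 ± 0.785 to 25.3 ± 7.09. The dehydrogenase gene dhs-14 (1.85 ± 0.184, SE) and cpt-5 (1.73 ± 0.188) rose, and Y54G2A.10 fell (-1.91 ± 0.169). Of 17 genes of mitochondrial fatty acid oxidation 4 rose, and adjusted over the list alone 7 rose and 1 fell (adjusted p = 0.408 with an estimated correlation). Of 9 branched-chain amino acid genes 2 rose, also adjusted over the list alone (adjusted p = 0.305 with an estimated correlation). Of 17 innate immunity genes 3 fell, 7 adjusted over the list alone (adjusted p = 0.235 with an estimated correlation).

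In that comparison 45 genes were higher and 20 lower (limma, Benjamini-Hochberg), 37 and 16 by at least 2-fold. The total of 65 became 25 without B12 replicate 1, 26 without B12 replicate 2, 26 without propionate replicate 1 and 11 without propionate replicate 2, and 9 of 28 named genes, including those above with a call, passed in each fit without a library. The difference from the wild type propionate response reached no call (0 genes in limma, 1775 at an unadjusted p under 0.05, 1 without wild type B12 replicate 1, 44 without wild type propionate replicate 1, 3 without the low-value filter and 2 with the replicate number as a block). The log2 difference was -3.08 ± 0.446 (SE) for acdh-1 (limma adjusted p = 0.0586), -1.4 ± 0.254 for ech-6 (0.131), -1.83 ± 0.311 for hach-1 (0.106), -1.58 ± 0.337 for hphd-1 (0.249), -0.51 ± 0.189 for alh-8 (0.383) and 1.08 ± 0.602 for acdh-2 (0.502). Adjusted over the list alone the responses of all 5 shunt genes were lower than in wild type (adjusted p = 0.187 with an estimated correlation). With the stage axes as covariates acdh-1 (-3.95) and hphd-1 (-2.28) passed. The 42 genes that propionate raised in wild type had a median log2 change of 1.65 there, 0.17 in nhr-10 mutants, where 8 were called higher, and 0.69 in nhr-68 mutants, where 13 were; the genes were chosen in wild type, which raises its value. The 53 genes that B12 lowered in wild type had medians of -1.6, -1.48 and -1.35, with 34 called lower in nhr-10 and 30 in nhr-68 mutants. Both sets depend on wild type B12 replicate 1: picked without it, 121 genes raised by propionate had medians of 1.26, -0.24 and 0.09, and 58 lowered by B12 had -1.53, -0.26 and -0.46. Without wild type propionate replicate 1, the raised genes had 1.84, -0.54 and 0.13. Leaving out other wild type libraries moved the mutants' medians the other way. The raised genes had 2.23, 0.30 and 0.95 without B12 replicate 2, and 2.02, 0.22 and 0.93 without propionate replicate 2. The lowered genes had -2.43, -2.39 and -2.15 without B12 replicate 2. They had -2.54, -1.98 and -2.15 without untreated replicate 1, and -2.59, -1.66 and -1.81 without untreated replicate 2.

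**Figure D2:**
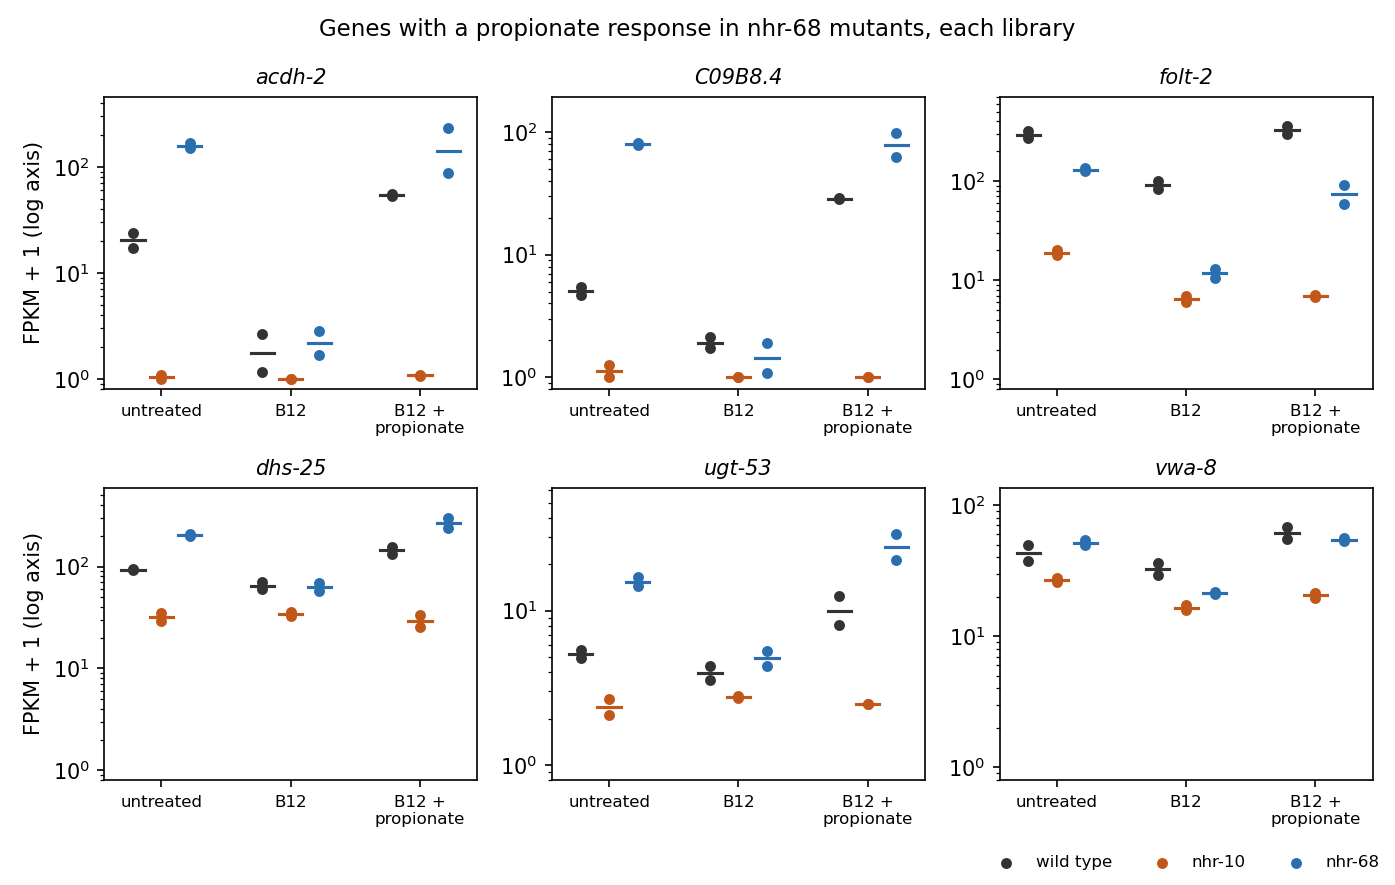
FPKM + 1 on a log axis of acdh-2, C09B8.4, folt-2, dhs-25, ugt-53 and vwa-8 in each treatment, with points for libraries and bars for the mean of 2, in wild type (black), nhr-10 mutants (orange) and nhr-68 mutants (blue). On B12 with propionate acdh-2 lies at 158 ± 101 FPKM in nhr-68 mutants and at 0.07 and 0.08 FPKM in the nhr-10 libraries.

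Untreated nhr-10 mutants had less of every shunt transcript than untreated wild type. acdh-1 was at 462 ± 182 FPKM against 2303 ± 347 (SD, n = 2; log2 -2.36 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 0.00222), ech-6 at 274 ± 54.3 against 789 ± 223, hach-1 at 58.4 ± 11.8 against 267 ± 88.2, hphd-1 at 67.7 ± 19.5 against 377 ± 73.9 and alh-8 at 193 ± 18.1 against 474 ± 17.9. All 5 were lower, also adjusted over the list alone (adjusted p = 0.0877 with an estimated correlation). folt-2 was lower by -3.96 ± 0.200, acdh-2 by -4.28 ± 0.426, zig-3 by -4.16 ± 0.358 and C23H5.8 by -2.55 ± 0.204. gst-4 (1.65 ± 0.211), gst-38 (1.58 ± 0.202), the cytochrome P450 gene cyp-13A2 (1.66 ± 0.234), the immune gene irg-2 (2.27 ± 0.289) and the collagen genes col-41 (3.1 ± 0.306) and col-176 (3.27 ± 0.417) were higher. Of 12 oxidative stress genes 2 were higher, 4 adjusted over the list alone (adjusted p = 0.232 with an estimated correlation), and of 138 collagens 5, 12 adjusted over the list alone. In limma with Benjamini-Hochberg adjustment 171 genes were higher and 46 lower, 141 and 39 by at least 2-fold. With median-ratio scaling the split was 128 and 74, and the median of all genes was 0.108 before it. The total of 217 became 87 without wild type replicate 1, 62 without wild type replicate 2, 67 without nhr-10 replicate 1 and 59 without nhr-10 replicate 2, and 18 of 37 named genes, including all those given here, passed in each fit without a library. The stage axes as covariates left 17 genes and ended the call of acdh-1 (-1.77, adjusted p = 0.141 in limma).

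On B12, nhr-10 mutants were lower than wild type in acdh-1 (0.16 ± 0.127 FPKM against 90.8 ± 35.8; SD, n = 2; log2 -6.25 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 8.9e-07), hphd-1 (16.15 ± 3.04 against 78.9 ± 0.495) and folt-2 (5.45 ± 0.651 against 90.4 ± 12.3). nhr-68 was at 9.12 ± 5.57 FPKM against 49.5 ± 1.19 and ech-6 at 92.2 ± 2.81 against 175 ± 2.96. The latter calls ended without wild type replicate 2 (limma adjusted p = 0.0505 and 0.0828) or nhr-10 replicate 1 (0.0557 and 0.105). Of 5 shunt genes 3 were lower, 4 adjusted over the list alone (adjusted p = 0.221 with an estimated correlation). Collagens moved in both directions, 22 higher and 28 lower of 138, 38 and 46 adjusted over the list alone, with col-147 (5.85 ± 0.769), col-149 (5.08 ± 0.562) and col-41 (3.18 ± 0.306) among those higher. Of 45 sperm markers 22 were higher, 37 adjusted over the list alone (adjusted p = 0.58 with an estimated correlation), of 20 oocyte and germline markers 8, 13 adjusted over the list alone (adjusted p = 0.708 with an estimated correlation), and of 6 vitellogenins 2, 5 adjusted over the list alone (adjusted p = 0.743 with an estimated correlation). The count was 1016 higher and 491 lower (limma, Benjamini-Hochberg; 704 and 340 by at least 2-fold), and 882 and 681 with median-ratio scaling. The 1507 became 920 without wild type replicate 1, 7.56% of the 1507 without wild type replicate 2, 101 without nhr-10 replicate 1 and 574 with only these groups in the fit, and 14 of 64 named genes passed in each fit without a library. With the stage axes as covariates 1 gene was left, acdh-1 (-4.93).

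For 4 of the 5 shunt genes the gap between nhr-10 mutants and wild type was widest on B12 with propionate; for alh-8 it was 2.17-fold, against 2.46-fold untreated. acdh-1 was at 0.3 ± 0.198 FPKM in nhr-10 mutants against 1734 ± 476 in wild type (SD, n = 2; log2 -10.36 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 2.13e-09), ech-6 at 121 ± 1.05 against 871 ± 38.8, hach-1 at 54.5 ± 5.71 against 466 ± 16.9, hphd-1 at 20.4 ± 5.73 against 379 ± 73.5 and alh-8 at 265 ± 44.3 against 573 ± 12.04. All 5 were lower, also adjusted over the list alone (adjusted p = 0.0877 with an estimated correlation). folt-2 was at 5.89 ± 0.240 FPKM against 327 ± 40.2, acdh-2 at 0.07 and 0.08 FPKM against 52.28 and 54.63, and C09B8.4 was listed at 0 in both nhr-10 libraries against 27.53 and 27.83. Higher were pccb-1 (1.11 ± 0.173), sams-1 (2.40 ± 0.278), the hydroxyacyl-CoA dehydrogenase gene hacd-1 (2.79 ± 0.254), gst-4 (2.03 ± 0.211), the cysteine synthase-like gene cysl-2 (3.20 ± 0.393) and the lectin gene clec-60 (3.35 ± 0.362). Of 7 canonical pathway genes 3 were higher, also adjusted over the list alone (adjusted p = 0.52 with an estimated correlation), of 9 hypoxia and hydrogen sulphide genes 5, also adjusted over the list alone (adjusted p = 0.52 with an estimated correlation), and of 17 innate immunity genes 4, 7 adjusted over the list alone (adjusted p = 0.506 with an estimated correlation).

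Moulting genes were higher in the same comparison, 8 of 16 (adjusted over the list alone 10 higher and 2 lower; adjusted p = 0.602 with an estimated correlation), among them mlt-11 (3.49 ± 0.451, SE) and noah-2 (3.49 ± 0.467), and of 138 collagens 14 were higher and 4 lower, 17 and 25 adjusted over the list alone (adjusted p = 0.81 with an estimated correlation), with col-41 at 5.08 ± 0.306. Altogether 872 genes were higher and 248 lower (limma, Benjamini-Hochberg), 611 and 115 by at least 2-fold. Without wild type replicate 2 the 1120 became 377 and without nhr-10 replicate 2 they became 206, and 13 with only these groups in the fit. Of 76 named genes 41 passed in each of the 4 fits without a library, all those just named with values among them. The stage axes as covariates left 21 genes, including all 5 shunt genes, acdh-2, C09B8.4 and folt-2.

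Untreated nhr-68 mutants also had low shunt transcripts but high acdh-2 and C09B8.4. acdh-1 was at 212 ± 35.3 FPKM against 2303 ± 347 in wild type (SD, n = 2; log2 -3.43 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 0.000174), ech-6 at 247 ± 27.2 against 789 ± 223 and hphd-1 at 81.6 ± 11.7 against 377 ± 73.9. C09B8.4 was at 79.1 ± 2.69 FPKM against 4.07 ± 0.552, and acdh-2 at 158 ± 11.6 against 19.5 ± 4.73. ivd-1, the isovaleryl-CoA dehydrogenase gene of leucine breakdown, was at 306 ± 0.580 FPKM against 75.0 ± 1.23, R09E10.2 at 218 ± 23.8 against 13.1 ± 3.70, and nra-2, which encodes a nicalin homologue bound to acetylcholine receptors, at 10.7 ± 0.240 against 95.6 ± 6.56. Of 5 shunt genes 4 were lower, also adjusted over the list alone (adjusted p = 0.232 with an estimated correlation); the fourth, hach-1 (-0.85), did not pass without wild type replicate 1 (-0.51, limma adjusted p = 0.277), nhr-68 replicate 1 (0.105) or nhr-68 replicate 2 (0.258). Without nhr-68 replicate 2, acdh-2 (2.89, limma adjusted p = 0.0611) and nhr-68 itself (-2.63, 0.0609) missed the threshold as well. Of 9 branched-chain genes 2 were higher, also adjusted over the list alone. Of 45 sperm markers 10 were lower and 1 higher, 14 and 1 adjusted over the list alone (adjusted p = 0.743 with an estimated correlation), and of 138 collagens 10 were higher, adjusted over the list alone 12 higher and 1 lower. There were 380 genes higher and 558 lower (limma, Benjamini-Hochberg), 294 and 149 by at least 2-fold. The 938 became 103 without wild type replicate 1, 197 without wild type replicate 2, 534 without nhr-68 replicate 1, 33 without nhr-68 replicate 2 and 165 with only these groups in the fit, and 14 of 53 named genes passed in each fit without a library. With the stage axes as covariates 5 were left, C09B8.4, R09E10.2, nra-2, Y58A7A.3 and col-41, and acdh-1 stood at -2.55 (adjusted p = 0.148 in limma).

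On B12 the nhr-68 mutants differed from wild type in acdh-1 (0.39 ± 0.0424 FPKM against 90.8 ± 35.8; SD, n = 2; log2 -5.99 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 6.22e-07), hphd-1 (18.2 ± 1.14 against 78.9 ± 0.495) and folt-2 (10.8 ± 1.76 against 90.4 ± 12.3). ivd-1 was at 217 ± 9.69 FPKM against 64.9 ± 3.06 and nra-2 at 9.21 ± 1.01 against 90.0 ± 4.74. Of 5 shunt genes 3 were lower, 4 adjusted over the list alone (adjusted p = 0.408 with an estimated correlation); the smallest change among them, ech-6 (-0.87), did not pass whichever of the 4 libraries was left out (limma adjusted p between 0.0583 and 0.096). The collagen genes col-8 (7.56 ± 1.157), col-147 (6.21 ± 0.769) and col-149 (5.43 ± 0.562) were higher, and of 138 collagens 22 were higher and 33 lower, 34 and 48 adjusted over the list alone. Of 6 vitellogenins 4 were higher, 6 adjusted over the list alone (adjusted p = 0.58 with an estimated correlation), of 45 sperm markers 12, 14 adjusted over the list alone (adjusted p = 0.761 with an estimated correlation), and of 20 oocyte and germline markers 4, 14 adjusted over the list alone (adjusted p = 0.661 with an estimated correlation). Of 49 cytochrome P450 genes 3 were higher and 7 lower, 8 and 14 adjusted over the list alone, and of 17 genes of mitochondrial fatty acid oxidation 3 were lower, 8 adjusted over the list alone (adjusted p = 0.698 with an estimated correlation). The count was 818 higher and 714 lower (limma, Benjamini-Hochberg; 641 and 509 by at least 2-fold). The 1532 became 632 without wild type replicate 1, 181 without wild type replicate 2, 184 without nhr-68 replicate 1 and 774 without nhr-68 replicate 2, and 20 of 69 named genes passed in each fit without a library. The stage axes as covariates left 2 genes, nra-2 (-2.78) and R09E10.2 (4.78), with acdh-1 at -4.53 (adjusted p = 0.0578 in limma).

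With propionate added, acdh-1 was at 2.22 ± 0.757 FPKM in nhr-68 mutants against 1734 ± 476 in wild type (SD, n = 2; log2 -9.07 ± 0.315, SE; limma, Benjamini-Hochberg adjusted p = 1.12e-08). ech-6 was at 180 ± 8.004 FPKM against 871 ± 38.8, hach-1 at 90.6 ± 21.3 against 466 ± 16.9, hphd-1 at 29.1 ± 0.912 against 379 ± 73.5 and folt-2 at 74.9 ± 23.3 against 327 ± 40.2. ivd-1 was higher, at 384 ± 6.29 against 82.7 ± 2.86, whereas acdh-2 (158 ± 101 against 53.5 ± 1.66; log2 1.38, limma adjusted p = 0.102) did not pass. Of 5 shunt genes 4 were lower, 5 adjusted over the list alone (adjusted p = 0.107 with an estimated correlation). Of 7 canonical pathway genes 1 was higher, 2 adjusted over the list alone. Of 138 collagens 10 were higher, 11 adjusted over the list alone, including col-41 (4.04 ± 0.306), and of 45 sperm markers 8 were lower, 14 adjusted over the list alone (adjusted p = 0.761 with an estimated correlation). The numbers were 184 higher and 304 lower (limma, Benjamini-Hochberg), 141 and 101 by at least 2-fold, and 269 and 261 with median-ratio scaling. The 488 became 67 without wild type replicate 1, 188 without wild type replicate 2, 44 without nhr-68 replicate 1, 91 without nhr-68 replicate 2 and 19 with only these groups in the fit, and 16 of 43 named genes, including all those given here with a call, passed in each fit without a library. The stage axes as covariates left 19 genes, among them acdh-1, ech-6, hach-1, hphd-1, ivd-1, nra-2 and nhr-68.

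The mutants shared many of their differences from wild type. Untreated, 128 genes differed in the same direction in both, 24 of them lower, where independent lists would share 4.17 higher and 1.65 lower. On B12 644 were higher in both and 392 lower in both against 53.4 and 22.5, and on B12 with propionate 121 and 86 against 10.3 and 4.84. These counts depend on single libraries. The untreated 128 ran from 18 without nhr-68 replicate 2 to 87 without nhr-68 replicate 1. On B12 the 1036 ran from 90 without wild type replicate 2 to 1239 without nhr-10 replicate 2, and with propionate the 207 from 28 without nhr-68 replicate 1 to 224 without nhr-10 replicate 1. When the stage axes were covariates 1 shared gene was left untreated, 0 on B12 in limma and 10 with propionate; on both axes the untreated libraries of both mutants lie above those of wild type. The correlation of log2 differences across genes was 0.708 untreated, 0.917 on B12 and 0.588 with propionate, where 100 simulated unchanged pairs of groups against the same wild type libraries gave 0.500, 0.500 and 0.501. The covariance was 0.205, 0.503 and 0.191 against 0.0441, 0.0441 and 0.0443. The 2 wild type libraries of a treatment cannot be split, so part of the excess may come from them. Between comparisons that share no library the correlation ran from 0.0814 to 0.681. In all 3 treatments 60 genes were higher and 20 lower in nhr-10 mutants than in wild type, and 71 and 34 in nhr-68 mutants. The 20 and the 34 each count a gene under 2 identifiers with the same differences, and the 34 include the deleted nhr-68 itself. The 80 genes of nhr-10 mutants ran from 26 without wild type untreated replicate 2 to 100 without nhr-10 propionate replicate 1, and the 105 of nhr-68 mutants from 20 without nhr-68 untreated replicate 2 to 109 without wild type propionate replicate 2; the stage axes as covariates left 0 and 2.

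**Figure D3:**
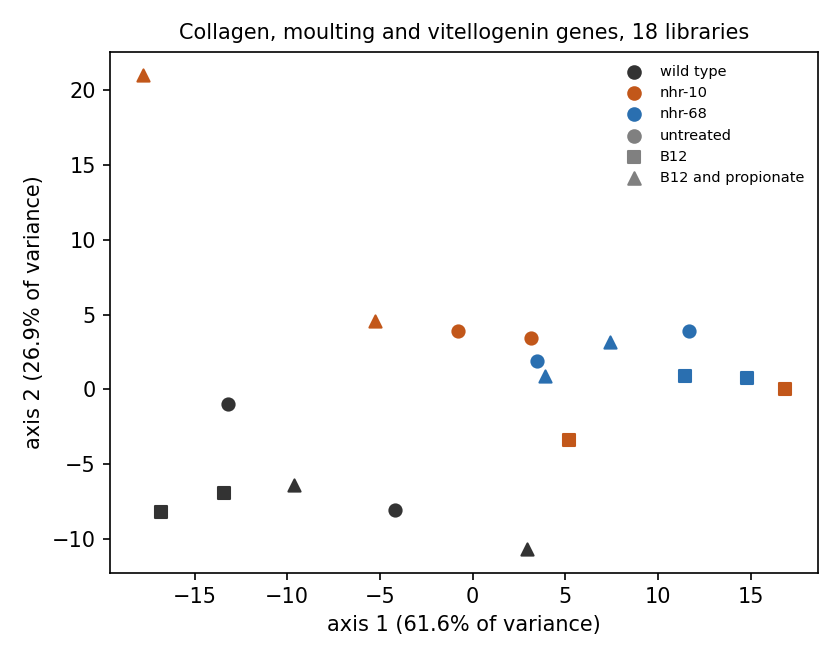
Position of each library on the axes drawn from 160 collagen, moulting and vitellogenin genes (axis units are principal component scores of log2 values), by genotype and treatment. Replicate 2 of the nhr-10 mutants on B12 with propionate lies at -17.8 and 21, away from the other libraries.

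Directly compared, untreated nhr-68 mutants had far more acdh-2 and C09B8.4 than untreated nhr-10 mutants. acdh-2 was at 158 ± 11.6 FPKM against 0.0400 ± 0.0566 (SD, n = 2; log2 7.25 ± 0.426, SE; limma, Benjamini-Hochberg adjusted p = 1.75e-06) and C09B8.4 at 79.1 ± 2.69 against 0.13 ± 0.184. folt-2 was at 130 ± 7.09 FPKM against 17.9 ± 1.63, dhs-25 at 204 ± 7.94 against 31.2 ± 4.09, ugt-53 at 14.4 ± 1.48 against 1.4 ± 0.396, ivd-1 at 306 ± 0.580 against 62.0 ± 14.9 and alh-8 at 403 ± 5.70 against 193 ± 18.1. The acyl-CoA dehydrogenase gene acdh-9 (1.11 ± 0.128) was higher, and nra-2 (-3.04 ± 0.127) and dod-24 (-1.79 ± 0.218) were lower. acdh-1 (-1.07), ech-6 (-0.14) and hphd-1 (0.29) did not pass, and hach-1 (1.29) lost its call whichever of the 4 libraries was left out (limma adjusted p between 0.0562 and 0.192). Of 5 shunt genes 2 were higher, and adjusted over the list alone 2 were higher and 1 lower (adjusted p = 0.58 with an estimated correlation). Of 9 branched-chain genes 2 were higher, 4 adjusted over the list alone (adjusted p = 0.11 with an estimated correlation). Of 13 peroxisomal fatty acid oxidation genes 1 was lower, 8 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation). There were 35 genes higher and 52 lower (limma, Benjamini-Hochberg; 29 and 36 by at least 2-fold), 64 and 27 with median-ratio scaling, which removed a shift of -0.164 in the median of all genes. The 87 became 53 without nhr-10 replicate 1, 28 without nhr-10 replicate 2, 43 without nhr-68 replicate 1, 27 without nhr-68 replicate 2, 134 with the replicate number as a block and 42 with only these groups in the fit, and 16 of 31 named genes passed in each fit without a library.

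On B12 with propionate the same genes stood apart. acdh-2 was at 158 ± 101 FPKM in nhr-68 against 0.0750 ± 0.00707 in nhr-10 mutants (SD, n = 2; log2 7.04 ± 0.426, SE; limma, Benjamini-Hochberg adjusted p = 1.25e-06), and C09B8.4 was at 61.22 and 96.79 FPKM against a listing of 0 in both nhr-10 libraries. folt-2 was at 74.9 ± 23.3 FPKM against 5.89 ± 0.240, dhs-25 at 267 ± 42.2 against 28.4 ± 5.71, ugt-53 at 25.3 ± 7.09 against 1.48 ± 0.0141 and ivd-1 at 384 ± 6.29 against 66.1 ± 1.27. acdh-9 (1.24 ± 0.128) and clec-47 (3.56 ± 0.508) were higher, and hacd-1 (-2.01 ± 0.254), gst-4 (-1.57 ± 0.211) and nra-2 (-2.99 ± 0.127) lower. acdh-1 (1.29, limma adjusted p = 0.0726), ech-6 (0.57), hach-1 (0.71) and hphd-1 (0.52) did not pass, and alh-8 (0.74) passed but not without nhr-10 replicate 1 (limma adjusted p = 0.07), nhr-68 replicate 1 (0.141) or nhr-68 replicate 2 (0.128). All 5 shunt genes were higher adjusted over the list alone (adjusted p = 0.235 with an estimated correlation). Of 9 branched-chain genes 2 were higher, also adjusted over the list alone (adjusted p = 0.137 with an estimated correlation), and of 9 hypoxia and hydrogen sulphide genes 1 was lower, 6 adjusted over the list alone (adjusted p = 0.52 with an estimated correlation). The vitellogenins had no call, and all 6 were higher adjusted over the list alone (adjusted p = 0.423 with an estimated correlation). In all 65 genes were higher and 134 lower (limma, Benjamini-Hochberg; 52 and 101 by at least 2-fold), 80 and 98 with median-ratio scaling, before which the median of all genes was -0.119. The 199 became 340 without nhr-10 replicate 1, 49 without nhr-10 replicate 2, 63 without nhr-68 replicate 1, 55 without nhr-68 replicate 2, 125 with a pseudocount of 0.1 and 19 with only these groups in the fit, and 17 of 36 named genes passed in each fit without a library. The stage axes as covariates left 32 genes.

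In the remaining groups no more than 3 members were called in any comparison. Body wall muscle markers (9 genes), neuron markers (13) and heat shock genes (10) had no call in any comparison in limma, and pharynx markers (12) had 1, lower in nhr-68 mutants than in wild type on B12. Intestine markers (11 genes) had 1 call in nhr-10 mutants against wild type on B12 and 2 in nhr-68 mutants, all higher. Of 78 cytosolic ribosomal protein genes 2 were higher in nhr-10 mutants against wild type on B12 with propionate and 1 lower in untreated nhr-68 mutants, none adjusted over the list alone. Of 9 genes of the mitochondrial unfolded protein response no more than 1 was called in any comparison. Of 12 genes of the endoplasmic reticulum unfolded protein response 2 rose with propionate in nhr-10 mutants, also adjusted over the list alone. In the same comparison 3 of 14 tricarboxylic acid and glyoxylate cycle genes rose, 5 adjusted over the list alone (adjusted p = 0.743 with an estimated correlation). Of 17 fatty acid synthesis genes 3 were higher in nhr-10 mutants than in wild type on B12 with propionate, 7 adjusted over the list alone (adjusted p = 0.612 with an estimated correlation), among them the desaturase gene fat-3 (1.51 ± 0.246). In total 195 of 532 list tests passed in camera with its preset correlation, and 0 did with an estimated correlation, where the lowest adjusted p was 0.0877.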

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

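All of the tests that weigh an explanation in this part were chosen after the result was seen.

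Responses that differed between a mutant and wild type in limma's test of the difference were the first to need a second look. For B12 this was so for 4 genes in nhr-10 mutants, acdh-1 (log2 difference -3.89), zig-3 (3.67), F55G11.2 (-1.77) and F14F9.4 (-1.6), and for 1 gene in nhr-68 mutants, C09B8.4 (-4.40). With only these groups in the fit none of these calls held, and that of C09B8.4 ended with a pseudocount of 0.1 as well (limma adjusted p = 0.161). For propionate it was so for 1323 genes in nhr-10 mutants, among them acdh-1 (-4.11), ech-6 (-1.92), hach-1 (-2.66), hphd-1 (-1.93) and alh-8 (-0.77). Fitting only the compared groups gave 4 calls for this propionate difference. acdh-1 was near 0 FPKM on B12 in both mutants, where the log2(FPKM + 1) scale compresses differences. Of the 1127 genes called for propionate within nhr-10 mutants, 65 were called also without propionate replicate 2 (5.77%) and 755 also without replicate 1.

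Mutants on B12 differed from wild type in 1507 genes (nhr-10) and 1532 genes (nhr-68), collagens and vitellogenins among them. Scaling is argued against as the whole source, since median-ratio scaling left 1563 and 1729 calls. For a difference in developmental stage at harvest, mutant minus wild type was correlated with the replicate differences of other groups, across called genes outside the stage lists. Each replicate difference was first turned to point the same way on the leading stage axis, drawn from the same libraries, which favours r above 0. The median r was 0.509 for nhr-10 (-0.00567 to 0.861, above 0 in 6 of 7 replicate pairs). For nhr-68 it was 0.651 (-0.192 to 0.847, 6 of 7). Both lowest values came from nhr-10 mutants on B12 with propionate, whose replicates lie far apart on that axis. Most pairs thus go with a stage difference. The replicates of this pair also lay apart on the other stage axis, at 4.57 and 21, which the test did not use. Its low r therefore does not decide for or against stage. With the stage axes as covariates 1 and 2 genes were left, but the axes follow genotype in this treatment, so a slower or faster development caused by the deletions cannot be told apart from a different time of harvest. A change of the deletions on these genes without any shift in stage stays open too.

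In nhr-68 mutants 16 genes, 8 higher and 8 lower, differed in the same direction from wild type in all 3 treatments and from nhr-10 mutants in both treatments tested, nra-2, ivd-1 and R09E10.2 among them. Without a library in turn 6 to 14 genes met this rule, and 2 with the stage axes as covariates. Of these, 5 lay within 20 kb of another member, against a median of 0 and at most 4 in 10000 random sets (permutation p = 1e-04, the smallest these draws can give), but among 38 genes that B12 changed in all genotypes 6 did as well (permutation p = 0.004), and the shares did not separate (one-sided Fisher's exact p = 0.178). That set, 39 genes with 1 lacking a position, ran from 12 without wild type untreated replicate 1 to 37 without nhr-10 untreated replicate 1, and was 25 without the low-value filter and 23 with the stage axes as covariates; the distances were not tested again on these. A variant in the background of the strain could give such runs, and so could shared regulation, so these cannot be told apart here. Neighbouring genes on chromosomes I and X were lower than in wild type in all 3 treatments in nhr-10 mutants too, and their positions were not tested. Linkage to the deleted gene is open as well, with 12.5% of the set within 2 Mb of nhr-68 against a random median of 6.25% (permutation p = 0.187). All nhr-68 libraries were deeper, 13900000 fragments or more, than those of the other genotypes, which may reflect a separate run and coincides with genotype.

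Untreated and on B12 with propionate, acdh-2 and C09B8.4 were high in nhr-68 mutants and near 0 in nhr-10 mutants; on B12 alone nhr-68 mutants had little of either (1.24 ± 0.813 and 0.495 ± 0.587 FPKM). Reads of the near-identical acdh-1 are argued against as the source of acdh-2 on B12 with propionate, since the lowest ratio of acdh-2 to acdh-1 in nhr-68 mutants there was 1310 times the highest in wild type. Untreated it was 16.107 times the highest, with acdh-1 above acdh-2 (ratios of 0.630 and 0.885). That is short of the 100-fold bound set for this test, so the test does not decide there. The untreated levels themselves argue against acdh-1 reads as the whole source. Wild type had more acdh-1 (2548.59 and 2058.19 FPKM against 237.43 and 187.44 in nhr-68 mutants) but less acdh-2 (16.18 and 22.87 against 149.53 and 165.95). Untreated nhr-10 mutants had 333.51 and 590.58 FPKM of acdh-1, with acdh-2 at 0.08 and 0. A candidate explanation is that nhr-10 acts on some propionate genes without nhr-68: of the 42 genes propionate raised in wild type, 10 were higher in nhr-68 than in nhr-10 mutants on B12 with propionate (alh-8, folt-2, C23H5.8, dhs-25, vwa-8, acdh-2, C09B8.4, ugt-53, hrg-10 and ZK6.6) and 0 lower, where independent lists would share 0.175. Without a library in turn 5 to 16 were higher, and 5 with the stage axes as covariates, with 0 lower in limma each time. Called for propionate were 9 of these within nhr-68 mutants and 0 within nhr-10 mutants in limma. Not all of the 10 were free of nhr-68. Untreated, on B12 and with propionate, folt-2 (-1.17, -2.96 and -2.14) was lower in nhr-68 mutants than in wild type. The same held for C23H5.8 (-1.61, -1.53 and -2.12). Untreated acdh-2 and C09B8.4 were higher in nhr-68 mutants than in wild type, which this explanation alone does not account for. A difference in the strains' backgrounds at the 10 genes was not tested. Action of nhr-10 without nhr-68 remains a hypothesis found and tested on the same data.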

How the results depend on the processing

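Every alternative here was planned except the stage axes, which were added after the data were seen; the cause of a change was not tested unless stated. Without a library in turn, 270 of the 764 calls of named genes held in every fit and 494 ended in at least 1. For 15 genes followed through all settings in every comparison, shunt and methionine genes among them, 1287 results without a library stayed on the same side of the threshold, 85 were weaker, 8 stronger and none turned direction with a call. Results called in neither fit count among the 1287, so that number is not a share of calls kept. The balance of all calls did turn with median-ratio scaling: from 43 higher and 53 lower to 55 and 49 for B12 and from 42 and 22 to 45 and 46 for propionate in wild type, 184 and 304 to 269 and 261 for nhr-68 mutants against wild type with propionate, 35 and 52 to 64 and 27 between the untreated mutants, and 550 and 773 to 800 and 722 for the propionate difference of nhr-10. Without a library in turn the count ran from 24 to 73 genes for B12 in wild type, 24 to 286 for propionate in wild type, 16 to 31 for B12 with propionate against untreated, 47 to 99 for B12 and 65 to 1071 for propionate in nhr-10 mutants, and 46 to 58 and 11 to 26 in nhr-68 mutants. Against wild type it ran from 59 to 87 untreated, 101 to 1910 on B12 and 206 to 1519 with propionate for nhr-10 mutants, and 33 to 534, 181 to 774 and 44 to 188 for nhr-68 mutants; between the mutants 27 to 53 untreated and 49 to 340 with propionate. For differences in response it ran from 1 to 17 and 1 to 2 for B12, and 45 to 2258 and 0 to 44 for propionate.

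A pseudocount of 0.1 gave 120 genes for propionate in wild type, 125 between the mutants with propionate and 0 for the B12 difference of nhr-68. No filter gave 7 for that difference, and 645 and 3 for the propionate differences of nhr-10 and nhr-68. Median-ratio scaling gave 5 for the B12 difference of nhr-68. Fitting only the compared groups leaves 2 residual degrees of freedom for 2 groups and also applies the filter to those libraries alone; these changes were not separated. It gave 1905 genes for nhr-68 mutants against wild type on B12 (1532 before), and fewer elsewhere among the counts that moved: 12 genes for B12, 2 for propionate and 0 for B12 with propionate in wild type, 21 for B12 and 0 for propionate in nhr-10 mutants, 574 and 13 for nhr-10 mutants against wild type on B12 and with propionate, 165 and 19 for nhr-68 mutants untreated and with propionate, 42 and 19 between the mutants, 0 and 0 for the B12 differences and 4 for the propionate difference of nhr-10; where limma gave 0 here, 639, 2629, 1156 and 987 genes lay under an unadjusted p of 0.05. The stage axes as covariates gave 25 for propionate in wild type, 64 for B12 and 8 for propionate in nhr-10 mutants, 17, 1 and 21 for nhr-10 and 5, 2 and 19 for nhr-68 mutants against wild type, 32 between the mutants with propionate, 2 for the B12 difference of nhr-68, 2 and 2 for the propionate differences, 1 shared gene of the untreated mutants (128 before) and 10 genes that propionate reversed (22 before). Estimating the correlation left 0 of 195 list tests in camera.

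The labels do not say that replicate numbers pair the samples. The correlation of same-numbered deviations over 36 pairs of groups ran from -0.379 to 0.563 (median 0.0801, 15 over 0.1). Mean log2 levels of the heat shock list were nonetheless higher in replicate 2 in each group except wild type on B12 (7.55 in replicate 1, 2.88 in replicate 2). Untreated, for example, they were 3.53 and 7.64 in nhr-10 and 3.15 and 7.02 in nhr-68 mutants. Variation shared by replicate number is thus not excluded. With the number as a block 109 genes were called for propionate in wild type, 134 between the untreated mutants, 2 for the propionate difference of nhr-68 and 37 reversed genes. The labels give no depth; the estimated 12600000 to 14200000 fragments limit genes near 0.1 FPKM.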

Other observations

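The comparisons and fits used for nhr-114 and acs-2 were planned; the run of genes on chromosome IV and the libraries high in hsp-16.2 were looked at after the results were seen.

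nhr-114, a nuclear hormone receptor gene, fell with B12 in each genotype: from 150 ± 17.4 to 39.5 ± 14.2 FPKM in wild type, from 136 ± 37.4 to 24.8 ± 5.52 in nhr-10 mutants and from 95.3 ± 3.03 to 21.3 ± 11.6 in nhr-68 mutants (SD, n = 2), with log2 changes of -1.94, -2.39 and -2.21. It stayed low with propionate, at 30.5 ± 6.08, 28.9 ± 1.75 and 20.3 ± 0.799 FPKM. In limma its call ended without wild type untreated replicate 1 (adjusted p = 0.193), untreated replicate 2 (0.102) or B12 replicate 1 (0.113), without nhr-10 untreated replicate 2 (0.0628) or B12 replicate 1 (0.059), and without nhr-68 untreated replicate 1 (0.0656), untreated replicate 2 (0.0624) or B12 replicate 1 (0.0564). acs-2, an acyl-CoA synthetase gene of fatty acid oxidation, was at 4.80 ± 0.898 FPKM on B12 and 241 ± 109 with propionate in nhr-10 mutants, and at 3.15 ± 0.0566 and 87.9 ± 37.2 in nhr-68 mutants. Its rise in nhr-10 mutants (5.32) was not called without propionate replicate 2 (4.84, limma adjusted p = 0.0559), and that in nhr-68 mutants (4.36) in none of the 4 fits without a library (adjusted p between 0.105 and 0.37).

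A run of 4 neighbouring genes on chromosome IV, between 5083303 and 5092807 of WBcel235, was higher in nhr-68 mutants than in wild type in all 3 treatments. The log2 differences untreated, on B12 and with propionate were 1.55, 1.63 and 1.32 for pygo-1, 2.02, 1.73 and 2.20 for ivd-1, 1.74, 1.85 and 1.068 for snpn-1, and 1.09, 1.13 and 0.91 for C02B10.4. The genes on either side, C02B10.6 (0.37, -0.01 and 0.16) and C02B10.3 (-0.29, -0.51 and 0.25), were not called in limma.

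hsp-16.2, a small heat shock gene, stood at 76.05 FPKM in wild type on B12 replicate 1, 65.56 in nhr-10 untreated replicate 2, 47 in nhr-68 untreated replicate 2, 30.0 in nhr-10 with propionate replicate 2 and 24.84 in nhr-68 with propionate replicate 2. In each case the other replicate of the group was at 2.66 or below, and no other library exceeded 7.52.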
